A study of Homo sapiens with 36 samples.

How the data were processed

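Transcripts were measured in 36 libraries of the breast cancer cell lines CAMA1, MCF7 and T47D, each as sensitive and as everolimus-resistant cells, after 12 h in DMSO or 10 nM everolimus, with 3 libraries in each of 12 groups. Per the labels' protocols, T47D cells grew in RPMI and the other lines in DMEM, RNA was isolated with the RNeasy Plus kit and stranded poly(A) libraries were made with the TruSeq Stranded mRNA kit. The protocols mention that cells were pooled at harvest without saying which, and do not state whether resistant cells were kept in everolimus between experiments. Per the submitters' processing notes the tools were STAR, given there with version 1.26, and RSEM 1.3.1, with the human genome build hg19 (GRCh37). The annotation and any filters are not given in the sources used here.

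A table of counts and a table of transcripts-per-million (TPM) values, both for 19371 gene symbols, were deposited by the authors. The deposited counts were whole numbers with totals of 4815155 to 16859472 per library, and whether they are rounded RSEM estimates is not stated. The deposited TPM columns had equal sums within rounding, as made by the authors. A total of 2067 genes had a count of 0 in every library, and 3600 table cells (0.516%) held a count of 0 beside a TPM above 0.5. No symbol began with the prefix of mitochondrially encoded genes. Genes are named by the symbols in the tables, and no coordinates were used. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, histone genes and MTRNR2L genes, may share reads and are uncertain.

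Groups and replicate numbers came from the sample labels. All 36 libraries were closest in expression to a library of their own group, and every pair of replicates differed by more than counting noise, with a chi-square per gene of 1.8 to 10.6. Counts were analyzed in R 4.3.3 with edgeR 4.0.16. For each line the 12 libraries entered one fit with 4 groups, after filterByExpr with the groups and TMM normalization, which kept 12151, 12692 and 12511 genes in CAMA1, MCF7 and T47D. Quasi-likelihood tests (glmQLFit and glmQLFTest) were made for everolimus against DMSO in sensitive and in resistant cells, for resistant against sensitive cells in DMSO, and for the interaction, each adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.0618, 0.0507 and 0.0711. Genes called in the same direction in all 3 lines were compared with the number independent lists would share. Whether an effect differed between lines was tested by a quasi-likelihood F test over all 36 libraries for the resistance effect and for the everolimus effect in sensitive cells.

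A set of 29 lists of pathways, complexes and cell type markers was tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, for lists with at least 5 measured members (328 tests). Each list is given with its genes called over all genes tested and with its genes called when adjusted over the list alone. Genes named in the text were taken by a fixed rule. It named SMARCD3 with the other SWI/SNF subunits and a set of receptor, drug target and growth genes, ESR1 to ABCB1. Per comparison it added the 6 highest and 6 lowest mean fold changes among genes called in the same direction in all lines with at least 5 CPM in the higher group, and per line the 3 highest and 3 lowest among called genes whose replicates do not overlap (for the interaction, among called genes) with at least 5 CPM. For each list described it took up to 2 highest and 2 lowest called members in the line described, and for some of these genes values in the other lines are given beside it. Most genes of the rule whose call in a line was lost when a single library was left out, with TPM or after thinning are not printed for that line. The comparisons, tests, lists, naming rule and the alternatives listed next, apart from the last 2, were made before the data were examined.

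Alternatives were RLE size factors, DESeq2 1.42.0, no filter and a stricter filter of 5 CPM in a group, the replicate number as a block, 1 fit of all 36 libraries, only the 6 libraries compared, glmTreat against a fold change of 1.5, limma on log2(TPM + 1) and log2(TPM + 0.1), resistant against sensitive cells under everolimus, camera with an estimated correlation and leaving out each library in turn. Thinning of counts to the smallest total of a line and list tests under everolimus were added after the data were seen. The procedure was tested on simulated counts with known changes, drawn from the means and library sizes of the resistance comparison. In 12030, 12559 and 12396 genes of CAMA1, MCF7 and T47D, changes of 1.5-fold were recovered for 65.7%, 76.1% and 77.6% of genes, of 2-fold for 88.1%, 91% and 91%, and of 4-fold for 98.5%, 100% and 100%, and 6.67%, 2.2% and 7.25% of calls were false. A fold against a group with 0 counts was set to a floor of 3 counts over the group. Depth intervals and floors cover counting error only.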

Results

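Gene expression was measured by RNA sequencing in 36 libraries from 3 estrogen receptor positive human breast cancer cell lines, CAMA1, MCF7 and T47D. Each line was studied as cells sensitive to everolimus and as an everolimus-resistant counterpart. Everolimus is a rapamycin analog that binds FKBP1A and inhibits mTOR complex 1, the kinase complex that couples nutrients and growth factors to protein synthesis and cell growth. Cells of each kind received the solvent DMSO or 10 nM everolimus for 12 h, which gave 12 groups of 3 libraries. The libraries held 4815155 to 16859472 counts. Everolimus libraries of sensitive CAMA1 were shallower, at 6906139 to 9589419, than their DMSO libraries, at 13474346 to 16236187. Both the smallest and the largest library were among the 3 of resistant MCF7 under everolimus. The labels call the libraries of a group biological replicates but do not state that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Markers of fibroblasts and endothelium passed the count filter for 4, 7 and 3 genes in CAMA1, MCF7 and T47D, and blood cell markers for 2, 0 and 0 genes. Values for the 3 lines follow the order CAMA1, MCF7 and T47D, and levels are mean counts-per-million (CPM) ± SD with n = 3. Fold changes are log2 values ± SE from fits with n = 3 libraries per group. This SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F, not a spread over 3 libraries. It can be too small where a group lies near 0 CPM.

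The first comparison asked how sensitive cells respond to 12 h of everolimus. In all 3 lines the drug lowered the genes that build ribosomes and the ATF4 targets, which supply amino acids and handle stress, and raised genes controlled by FOXO transcription factors, which growth factor signaling holds inactive. SLC7A11, the cystine and glutamate exchanger, fell by a log2 fold change of -1.44 ± 0.15, -1.90 ± 0.08 and -0.88 ± 0.15, in MCF7 from 61.9 ± 3.15 to 16.6 ± 0.541 CPM. KLHL24, from the FOXO list, rose by 2.43 ± 0.09, 1.76 ± 0.09 and 1.57 ± 0.07, in MCF7 from 12.0 ± 1.56 to 40.4 ± 3.22 CPM. The genes of the G1/S transition and DNA replication fell almost as a group in CAMA1 and T47D, and much less in MCF7.

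Among 11306 genes tested in every line, 789 rose and 1056 fell in all 3 lines, where independent lists would share 105 and 125 by direction. The shared increases were led by YPEL1 (2.62 ± 0.15, 2.06 ± 0.22 and 1.61 ± 0.20), KLHL24 and TCP11L2 (2.72 ± 0.16, 1.19 ± 0.17 and 1.76 ± 0.23). CREBRF, a regulator of the CREB3 stress factor, rose by 2.11 ± 0.08 and 1.62 ± 0.12 in CAMA1 and T47D. FBXO32, the ubiquitin ligase atrogin-1 and a known FOXO target, rose by 2.46 ± 0.10, 1.52 ± 0.16 and 0.80 ± 0.07. CALCOCO1, an autophagy receptor, rose by 1.81 ± 0.08, 1.45 ± 0.12 and 1.09 ± 0.11. Shared decreases were led by SLC7A11. GALE, the UDP-galactose epimerase, fell by -1.81 ± 0.13, -0.93 ± 0.10 and -0.92 ± 0.11 and the organic anion transporter gene SLCO4A1 by -1.72 ± 0.17, -0.76 ± 0.08 and -1.42 ± 0.20. The alpha-tubulin gene TUBA4A fell by -1.45 ± 0.14, -1.22 ± 0.20 and -1.08 ± 0.09, FAM222A by -1.43 ± 0.12, -1.30 ± 0.15 and -1.25 ± 0.20 and P2RY6, a receptor for uridine nucleotides, by -1.96 ± 0.30, -1.62 ± 0.24 and -0.49 ± 0.12.

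Of the 36 ribosome biogenesis genes, 35, 35 and 30 were lower under everolimus, with list medians of -0.64, -0.54 and -0.42 and camera adjusted p (Benjamini-Hochberg) of 3.02e-23, 6.93e-35 and 1.23e-19. NOP16, a nucleolar protein of the large subunit pathway, fell by -1.09 ± 0.08, -0.88 ± 0.08 and -1.07 ± 0.11, MRTO4 by -1.05 ± 0.07, -0.71 ± 0.07 and -0.91 ± 0.10 and RRP12 by -0.66 ± 0.07, -0.96 ± 0.07 and -0.63 ± 0.06. ATF4 targets were lower for 22 of 28, 23 of 28 and 20 of 29 measured genes (22, 23 and 21 adjusted over the list alone), with medians of -0.60, -0.55 and -0.41. CHAC1, which degrades glutathione, fell by -1.96 ± 0.24 and -2.53 ± 0.23 in CAMA1 and MCF7. The large neutral amino acid transporter SLC7A5 fell by -1.36 ± 0.06 and -0.90 ± 0.06 in MCF7 and T47D, and its effect differed between lines (edgeR, Benjamini-Hochberg adjusted p = 1.36e-11). DDIT4, an inhibitor of mTOR complex 1, fell by -2.16 ± 0.13 in CAMA1 and -0.54 ± 0.09 in MCF7 but was not called in T47D at 0.15 ± 0.13, and the lines differed (edgeR, Benjamini-Hochberg adjusted p = 5.75e-13).

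FOXO-regulated genes were higher for 15 of 21, 14 of 22 and 13 of 21 measured genes (15, 15 and 15 adjusted over the list alone), with medians of 0.56, 0.37 and 0.45. Besides KLHL24 they included TXNIP, which binds thioredoxin and restrains glucose uptake (1.83 ± 0.06, 1.10 ± 0.06 and 0.75 ± 0.08), CCNG2, the gene of cyclin G2 (1.52 ± 0.08, 0.91 ± 0.10 and 1.10 ± 0.09), and PIK3IP1, an inhibitor of PI3-kinase (0.71 ± 0.16, 1.51 ± 0.20 and 0.76 ± 0.21). Among receptor genes, INSR, the insulin receptor, rose by 0.56 ± 0.07, 0.65 ± 0.07 and 0.42 ± 0.11 and ERBB3 by 0.54 ± 0.05, 0.30 ± 0.06 and 0.43 ± 0.06, and ERBB2 rose by 0.76 ± 0.05 and 0.43 ± 0.06 in CAMA1 and MCF7. FGFR4 fell by -0.43 ± 0.05, -0.83 ± 0.13 and -0.67 ± 0.15. DEPTOR, a protein that binds and inhibits mTOR, rose by 1.13 ± 0.09, 1.06 ± 0.11 and 0.76 ± 0.09. In CAMA1 the estrogen response list was higher for 15 of 26 genes (17 adjusted over the list alone, median 0.26), with PGR, the progesterone receptor and an estrogen-induced gene, up by 1.70 ± 0.08 and GREB1 by 1.15 ± 0.07. That list missed the camera threshold in MCF7 and T47D (camera, Benjamini-Hochberg adjusted p = 0.0891 and 0.0912), a difference between lines not tested for the list.

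G1/S and replication genes were lower for 38 of 39 in CAMA1 (median -0.69) and 38 of 39 in T47D (median -0.73). In MCF7 14 were lower and 3 higher (15 and 4 adjusted over the list alone) and the median was -0.13, with camera adjusted p (Benjamini-Hochberg) of 0.0399 and adjusted p = 0.198 with an estimated correlation. The MCF7 list call was also lost when sensitive DMSO replicate 1, everolimus replicate 1 or everolimus replicate 2 was left out (camera, Benjamini-Hochberg adjusted p = 0.0544, 0.0545 and 0.0717) and with the stricter filter or thinned counts (0.0671 and 0.134). Single genes of the list responded differently between the lines for 37 of 39. The replication factor MCM10 fell by -1.34 ± 0.07, -0.51 ± 0.06 and -1.30 ± 0.07 and the phosphatase gene CDC25A by -1.78 ± 0.11, -0.48 ± 0.09 and -1.13 ± 0.10, and the helicase subunit CDC45 fell by -0.68 ± 0.07 and -1.18 ± 0.10 in CAMA1 and T47D. Lipid synthesis genes also fell. Fatty acid synthesis genes were lower for 7 and 9 of 15 genes in CAMA1 and MCF7 (7 and 9 adjusted over the list alone), with ACLY, the source of cytosolic acetyl-CoA, down by -0.52 ± 0.05, -0.51 ± 0.05 and -0.41 ± 0.05 in the 3 lines. For cholesterol synthesis 17, 19 and 14 of 23 genes were lower (17, 19 and 15 adjusted over the list alone), and camera kept the call with an estimated correlation in CAMA1 but not in the others (camera, Benjamini-Hochberg adjusted p = 0.0771 and adjusted p = 0.0862 with an estimated correlation). DHCR7, the last enzyme of cholesterol synthesis, fell by -1.04 ± 0.10, -0.55 ± 0.05 and -0.37 ± 0.06.

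By line, edgeR's quasi-likelihood test called 6297 of 12151, 5001 of 12692 and 4396 of 12511 genes at a Benjamini-Hochberg threshold of 0.05, of which 618, 209 and 182 changed at least 2-fold. Higher against lower genes numbered 3148 and 3149, 2413 and 2588, and 2286 and 2110. With limma on log2(TPM + 1) these splits became 4201 and 1867, 1338 and 2658, and 2920 and 1288, so the balance of directions depended on the scaling.

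**Figure D1:**
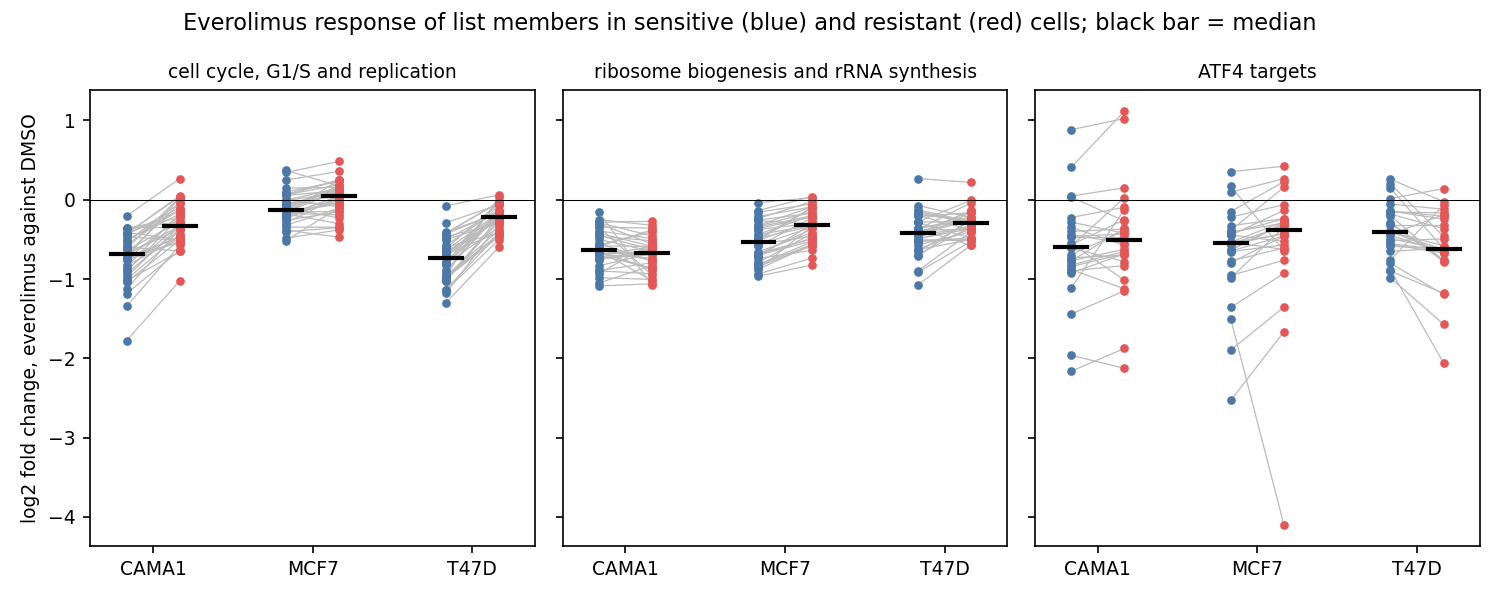
Log2 fold changes under everolimus of the genes of 3 lists (ribosome biogenesis, ATF4 targets, G1/S and replication) in the 3 lines, one point per gene, with sensitive cells in blue, resistant cells in red and the list median as a black bar, and gray lines joining the values of a gene. The G1/S medians of CAMA1 moved from -0.69 in sensitive to -0.33 in resistant cells, while those of ribosome biogenesis stayed at -0.64 and -0.67.

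The second comparison asked whether resistant cells still respond to the drug. They did in each line, and with many of the same genes. Ribosome biogenesis genes and ATF4 targets fell again in all 3 lines, and FOXO-regulated genes rose, although the calls of the ATF4 list in CAMA1 and the FOXO list in T47D were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0573 and 0.145). SLC7A11 fell by -1.15 ± 0.15, -1.35 ± 0.10 and -2.06 ± 0.15, in T47D from 38.8 ± 4.20 to 9.22 ± 1.73 CPM, and KLHL24 rose by 2.95 ± 0.10, 1.17 ± 0.07 and 0.79 ± 0.07, in CAMA1 from 15.5 ± 1.61 to 119 ± 16.3 CPM. Both everolimus comparisons used separate libraries, and 4534, 2472 and 998 genes were called in the same direction in both against 109, 32 and 77 in opposite directions. The fold changes correlated across genes with Pearson r of 0.78, 0.53 and 0.44, where genes are not independent replicates.

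In resistant cells 336 genes rose and 487 fell in all 3 lines, where independent lists would share 80.2 in all. Apart from YPEL1 (3.31 ± 0.17, 1.80 ± 0.25 and 1.24 ± 0.20) and KLHL24, the increases were led by MYO15B (3.07 ± 0.25, 1.16 ± 0.16 and 1.11 ± 0.19) and CALCOCO1 (2.46 ± 0.08, 1.18 ± 0.11 and 0.85 ± 0.10). The decreases included IFRD1 (-1.74 ± 0.07, -0.98 ± 0.08 and -0.58 ± 0.12), DDIT4 (-1.88 ± 0.13, -0.63 ± 0.08 and -0.62 ± 0.13), CCDC86 (-1.39 ± 0.15, -0.91 ± 0.09 and -0.73 ± 0.07) and the translation initiation factor gene EIF5 (-1.23 ± 0.06, -0.81 ± 0.05 and -0.45 ± 0.06).

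Ribosome biogenesis genes were lower for 36, 26 and 26 of 36 (36, 27 and 32 adjusted over the list alone), with medians of -0.67, -0.32 and -0.30 and camera adjusted p (Benjamini-Hochberg) of 3.55e-28, 3.18e-18 and 3.76e-20. UTP20 fell by -0.76 ± 0.06, -0.74 ± 0.06 and -0.58 ± 0.07 and RRP12 by -0.87 ± 0.07, -0.83 ± 0.07 and -0.50 ± 0.06. ATF4 targets were lower for 21 of 28, 20 of 28 and 21 of 29 genes (21, 21 and 21 adjusted over the list alone), with medians of -0.51, -0.38 and -0.62, and the CAMA1 call was lost by camera at a Benjamini-Hochberg adjusted p = 0.0573 with an estimated correlation. CHAC1 fell by -2.13 ± 0.20, -1.67 ± 0.27 and -1.57 ± 0.24. FOXO-regulated genes were higher for 14 of 21, 14 of 22 and 7 of 21 genes (15, 14 and 8 adjusted over the list alone), and the T47D call was lost by camera at a Benjamini-Hochberg adjusted p = 0.145 with an estimated correlation. CCNG2 rose by 1.86 ± 0.09, 0.58 ± 0.10 and 0.53 ± 0.09 and DEPTOR by 1.19 ± 0.09, 0.82 ± 0.10 and 0.45 ± 0.09. In CAMA1 and MCF7 INSR rose by 0.97 ± 0.07 and 0.87 ± 0.07 and FGFR4 fell by -0.37 ± 0.06 and -0.84 ± 0.17.

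G1/S genes were lower for 26 of 39 in resistant CAMA1 (27 adjusted over the list alone) and 19 of 39 in T47D (23 adjusted over the list alone), with medians of -0.33 and -0.22, and the CAMA1 call was lost by camera at a Benjamini-Hochberg adjusted p = 0.0573 with an estimated correlation. CDC25A fell by -1.02 ± 0.10, -0.38 ± 0.09 and -0.43 ± 0.09 and CDC6, which loads the replicative helicase, by -0.64 ± 0.07, -0.35 ± 0.06 and -0.50 ± 0.06. MCF7 showed no shift of this list by camera (Benjamini-Hochberg adjusted p = 0.684). In resistant MCF7 cholesterol synthesis genes were lower for 19 of 23 genes (20 adjusted over the list alone) and fatty acid synthesis genes for 9 of 15 (9 adjusted over the list alone), with MSMO1 down by -0.65 ± 0.07, MVK, mevalonate kinase, by -0.52 ± 0.10 and SCD, stearoyl-CoA desaturase, by -0.49 ± 0.05. YAP and TAZ targets were higher there for 9 of 14 genes (11 adjusted over the list alone), with ANKRD1 up by 1.31 ± 0.32 and CTGF, a matricellular growth factor, by 0.87 ± 0.16. In resistant CAMA1 the luminal markers were higher for 12 of 16 genes (12 adjusted over the list alone), with XBP1, a transcription factor of the secretory pathway, up by 0.88 ± 0.05. How these list responses differ between lines was not tested in resistant cells.

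The test called 6795, 3660 and 1950 genes (3447 and 3348 higher and lower in CAMA1, 1899 and 1761 in MCF7, 960 and 990 in T47D), of which 790, 118 and 91 changed at least 2-fold. With limma on log2(TPM + 1) the splits became 3950 and 2020, 1207 and 1913, and 420 and 937, and 151 and 463 for genes shared by all lines. Without resistant everolimus replicate 1 or 2 the T47D count was 994 or 1040, and the count shared by all lines 464 or 496.

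The third comparison asked how resistant cells differ from sensitive cells when both are in DMSO. SMARCD3, the SWI/SNF subunit BAF60c that the title of the series names, was higher in resistant cells of every line. Its log2 fold changes were 1.55 ± 0.28, 1.31 ± 0.18 and 1.66 ± 0.25, with levels of 1.19 ± 0.306 to 3.56 ± 0.402 CPM in CAMA1, 3.43 ± 0.475 to 8.52 ± 0.728 CPM in MCF7 and 1.73 ± 0.275 to 5.68 ± 1.00 CPM in T47D (edgeR, Benjamini-Hochberg adjusted p = 1.06e-04, 3.94e-08 and 1.05e-05). The lines did not differ detectably in this effect (edgeR, Benjamini-Hochberg adjusted p = 0.602). Everolimus for 12 h gave no call for SMARCD3 in sensitive (0.13 ± 0.36, -0.24 ± 0.21 and -0.18 ± 0.30) or resistant cells (-0.22 ± 0.25, -0.08 ± 0.17 and -0.28 ± 0.21). Otherwise resistant and sensitive cells differed in largely different ways in the 3 lines. Several receptor genes and the MAPK feedback gene DUSP4 changed in opposite directions. The samples hold a single resistant counterpart per line, so an effect of resistance cannot be told apart from other differences between those cultures. Nor do the protocols state whether resistant cells were kept in everolimus before, so earlier drug may still act in their DMSO groups.

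**Figure D2:**
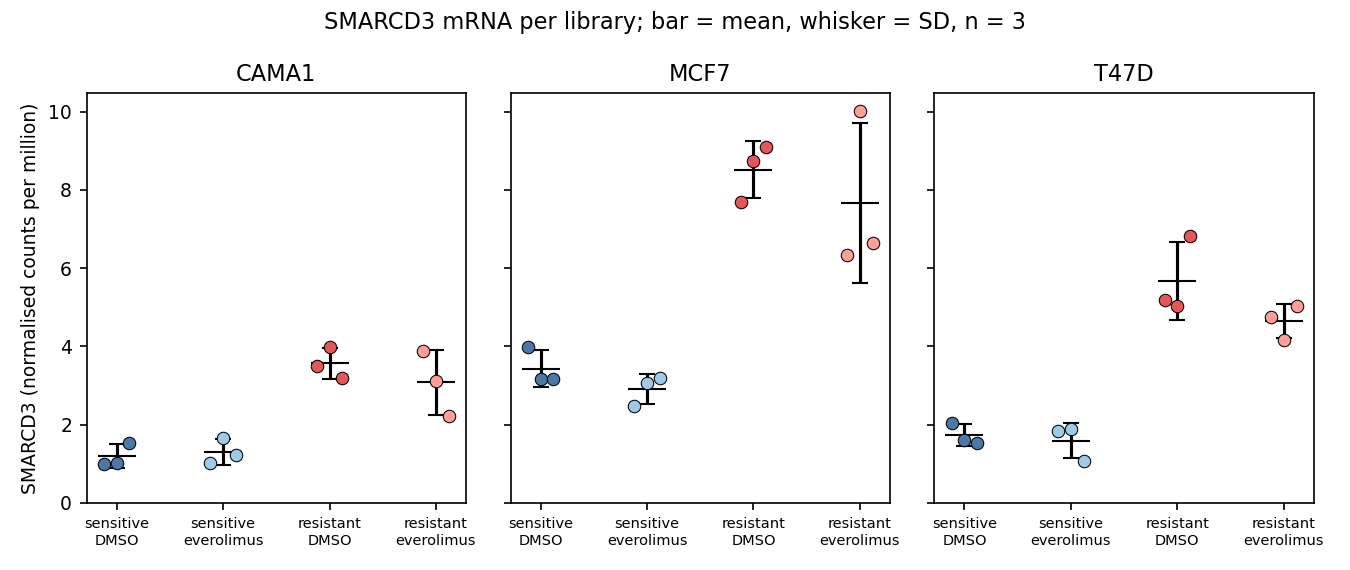
SMARCD3 expression in CPM in the 12 groups, one point per library, with the mean as a bar and the SD as whiskers (n = 3). Mean levels in DMSO rose from 1.19 to 3.56 CPM in CAMA1, from 3.43 to 8.52 in MCF7 and from 1.73 to 5.68 in T47D.

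The other SWI/SNF subunits changed in both directions, and their sizes of change were not tested against that of SMARCD3. PHF10, a subunit of the PBAF complex, fell by -1.31 ± 0.19 and -0.39 ± 0.08 in CAMA1 and MCF7, without a call in MCF7 with both states under everolimus (-0.027). DPF2 rose by 0.77 ± 0.05 in CAMA1 and fell by -0.67 ± 0.07 in MCF7 (line difference by edgeR, Benjamini-Hochberg adjusted p = 7.96e-16). SMARCA2, one of the ATPases, fell by -0.72 ± 0.07 in T47D. Subunits higher and lower numbered 5 and 3 of 26 in CAMA1, 12 and 6 of 27 in MCF7, and 5 and 9 of 26 in T47D (adjusted over the list alone 5, 12 and 6 higher and 2, 6 and 10 lower), and camera gave no call (Benjamini-Hochberg adjusted p = 0.513, 0.429 and 0.386). MTOR itself rose by 0.38 ± 0.05 and 0.35 ± 0.07 in MCF7 and T47D. Its change in CAMA1 was 0.207, and the lines did not differ detectably (edgeR, Benjamini-Hochberg adjusted p = 0.0939).

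A total of 259 genes were higher and 307 lower in resistant cells of all 3 lines, against 367 shared by independent lists, and 1205 other genes were called in all 3 lines with directions that differed. The number 367 takes every gene as equally likely to be called, so an excess over it need not mean a shared direction. The shared increases were led by PTGES, the inducible prostaglandin E synthase (2.87 ± 0.09, 2.78 ± 0.21 and 1.35 ± 0.06), and the secreted hormone STC1 (1.25 ± 0.07, 1.66 ± 0.10 and 2.01 ± 0.10). SLC7A2, a transporter of arginine and lysine, rose by 0.95 ± 0.05, 0.59 ± 0.05 and 2.66 ± 0.12. ZNF703, a transcriptional repressor amplified in some luminal tumors, rose by 1.28 ± 0.08, 0.89 ± 0.08 and 1.77 ± 0.11. In CAMA1 PTGES went from 9.63 ± 1.14 to 70.1 ± 3.00 CPM. Shared decreases included the actin-severing protein SCIN (-0.32 ± 0.06, -9.34 ± 0.17 and -1.13 ± 0.13) and KYNU, an enzyme of tryptophan breakdown (-1.97 ± 0.07, -1.82 ± 0.06 and -0.54 ± 0.07). C1orf115 fell by -1.72 ± 0.09, -0.68 ± 0.15 and -0.66 ± 0.12 and ARID5B by -1.70 ± 0.07 and -1.20 ± 0.13 in MCF7 and T47D. SCIN in MCF7 fell from 101 ± 1.69 to 0.140 ± 0.122 CPM, so near 0 that the size of its fold change is uncertain and its SE may be too small. Among list members, the growth factor receptor IGF1R rose by 0.88 ± 0.08, 0.97 ± 0.06 and 0.55 ± 0.09, but with both states under everolimus its T47D difference was 0.058 and not called.

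**Figure D3:**
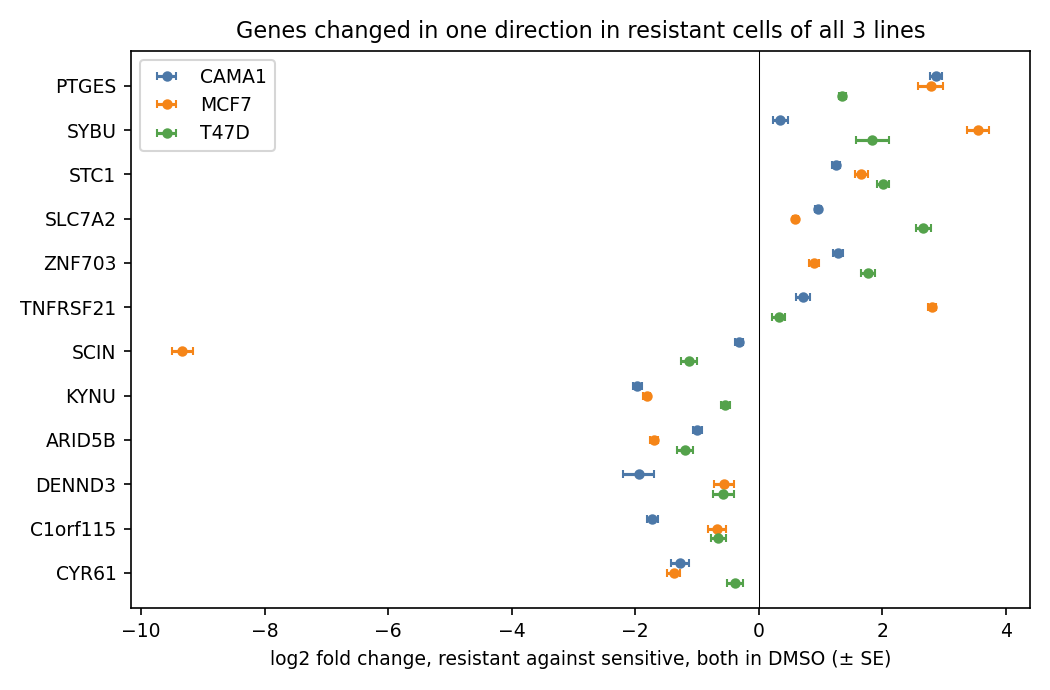
Log2 fold changes, resistant minus sensitive cells in DMSO, of the 12 genes with the largest mean change among those called in the same direction in all 3 lines, with SE as whiskers and one color per line. PTGES rose by 2.87, 2.78 and 1.35 and KYNU changed by -1.97, -1.82 and -0.54 in CAMA1, MCF7 and T47D.

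Hormone and growth factor receptors differed by line. ESR1, the estrogen receptor, rose by 0.75 ± 0.05 in CAMA1 and 0.56 ± 0.06 in T47D, with -0.11 ± 0.05 and no call in MCF7 (line difference by edgeR, Benjamini-Hochberg adjusted p = 1.00e-13). PGR fell by -1.85 ± 0.09 and -0.79 ± 0.08 in CAMA1 and MCF7 and rose by 0.27 ± 0.08 in T47D (line difference by edgeR, Benjamini-Hochberg adjusted p = 4.56e-19). The T47D call for PGR was lost without sensitive DMSO replicate 2 or resistant DMSO replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0657 and 0.0721), and with both states under everolimus the direction turned to -0.653. ERBB2 fell by -1.08 ± 0.06 in CAMA1 and rose by 0.27 ± 0.07 and 0.64 ± 0.08 in MCF7 and T47D, where the MCF7 call was lost with limma on log2(TPM + 1) at a Benjamini-Hochberg adjusted p of 0.0965. ERBB4 fell by -1.32 ± 0.08 in CAMA1 and rose by 2.27 ± 0.06 in MCF7. EGFR rose by 2.53 ± 0.15 in MCF7, was not called in T47D at 0.17 ± 0.13 (-0.559 under everolimus) and was below the count filter in CAMA1. FGFR1 fell in MCF7 (edgeR, Benjamini-Hochberg adjusted p = 4.10e-10) and rose by 0.55 ± 0.10 in T47D. For ERBB2, ERBB4, EGFR and FGFR1 the edgeR test of a line difference gave Benjamini-Hochberg adjusted p values of 2.15e-19, 3.75e-28, 2.39e-11 and 6.31e-12. FKBP1A, the protein everolimus binds, fell by -0.29 ± 0.07 in MCF7, and the drug efflux pump gene ABCB1 was below the filter in each line.

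MAPK output genes were lower in resistant CAMA1 for 9 of 15 (9 adjusted over the list alone), with a camera Benjamini-Hochberg adjusted p of 0.00401 and adjusted p = 0.0615 with an estimated correlation. With both states under everolimus the list had no camera call (Benjamini-Hochberg adjusted p = 0.357, median -0.426 against -0.82 in DMSO). DUSP6, an ERK phosphatase and feedback gene, fell by -2.02 ± 0.23 in CAMA1 and -1.21 ± 0.13 in T47D and was not called in MCF7 at 0.33 ± 0.22 (line difference by edgeR, Benjamini-Hochberg adjusted p = 3.02e-09). DUSP4 fell by -3.25 ± 0.36 in CAMA1 and rose by 1.09 ± 0.07 in MCF7 (adjusted p = 1.41e-19 by edgeR with Benjamini-Hochberg). Cyclin D1, CCND1, fell by -0.23 ± 0.05 in CAMA1 (-0.024 and no call with both states under everolimus) and rose by 0.52 ± 0.05 and 0.54 ± 0.06 in MCF7 and T47D, and MYC rose by 0.43 ± 0.06 in CAMA1. The line differences of CCND1 and MYC gave edgeR Benjamini-Hochberg adjusted p values of 7.58e-15 and 2.77e-08.

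G1/S and replication genes were lower in resistant cells for 17, 31 and 31 of 39 genes (18, 31 and 31 adjusted over the list alone), with medians of -0.15, -0.31 and -0.31. The camera call held with an estimated correlation in T47D, but not in CAMA1 or MCF7 (camera, Benjamini-Hochberg adjusted p = 0.506 and adjusted p = 0.0645 with an estimated correlation), and in CAMA1 it was also lost without sensitive DMSO replicate 1 or 3 or resistant DMSO replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0653, 0.069 and 0.0622) and with RLE factors, the stricter filter or thinned counts (0.0504, 0.0554 and 0.0608). With both states under everolimus the list turned to higher in CAMA1 (median 0.263, 21 genes higher and 1 lower) and T47D (median 0.183, 17 and 3), so its lower level in these lines held in DMSO only. The higher level under everolimus had no call with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.225 and 0.342). MCM5, of the replicative helicase, was lower by -0.61 ± 0.06, -0.53 ± 0.07 and -0.45 ± 0.07. Under everolimus its difference was 0.338 in T47D and 0.142 without a call in CAMA1 (edgeR, Benjamini-Hochberg adjusted p = 0.102). Ribosomal protein genes were higher for 56 and 56 of 77 in resistant CAMA1 and MCF7 and lower for 66 in T47D (56, 56 and 69 adjusted over the list alone), with medians of 0.21, 0.27 and -0.47. None of these 3 ribosomal protein calls held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.606, 0.674 and adjusted p = 0.520 with an estimated correlation), and 76 of 77 genes differed between lines. RPL29 rose by 0.85 ± 0.06 in MCF7.

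Other changes are given for the line in which they were named, without a claim that the other lines lacked them. In resistant MCF7 p53 targets were higher for 13 of 20 genes (13 adjusted over the list alone, median 0.52), a call that held with an estimated correlation in DMSO but not with both states under everolimus (camera, Benjamini-Hochberg adjusted p = 0.0972), with the cell cycle inhibitor CDKN1A up by 2.57 ± 0.06 and ZMAT3 by 1.94 ± 0.09. TP63, a transcription factor of basal epithelium, rose by 5.56 ± 0.17, the proteoglycan gene SPOCK1 by 7.03 ± 0.14 and VIM, the intermediate filament vimentin, by 3.51 ± 0.43, while the serine synthesis enzyme gene PSAT1 fell by -7.16 ± 0.27. AREG, a ligand of EGFR, rose by 3.88 ± 0.15. In resistant CAMA1 the adhesion receptor CD44 rose by 5.90 ± 0.20, from 0.783 ± 0.243 to 48.1 ± 4.96 CPM, and the neurotrophin receptor gene NTRK2 by 3.62 ± 0.30, while the luminal secreted proteins AGR2 and TFF3 fell by -3.91 ± 0.13 and -3.57 ± 0.28 and the adhesion protein CEACAM6 by -4.48 ± 0.33. In resistant T47D fatty acid synthesis genes were higher for 10 of 15 (10 adjusted over the list alone), a call that held with an estimated correlation in DMSO but not with both states under everolimus (camera, Benjamini-Hochberg adjusted p = 0.222). PSAT1, lower in MCF7, rose by 2.93 ± 0.10 (line difference by edgeR, Benjamini-Hochberg adjusted p = 9.94e-29). SIGLEC6, a sialic acid binding lectin, rose by 7.41 ± 0.23 and the transcription factor SOX5 by 5.41 ± 0.30, while GFRA1, the receptor subunit for GDNF, fell by -4.42 ± 0.12 and the potassium channel KCNJ2 by -5.80 ± 0.28.

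The test called 5283, 8286 and 5714 genes, of which 761, 1677 and 782 differed at least 2-fold. Higher against lower genes numbered 2636 and 2647, 4060 and 4226, and 2838 and 2876, and with limma on log2(TPM + 1) the MCF7 split became 2990 and 4657, the T47D split 4348 and 1233, and that of the genes shared by all lines 246 and 177. A test over all 36 libraries found 9205 genes whose resistance effect differed between lines.

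**Figure D4:**
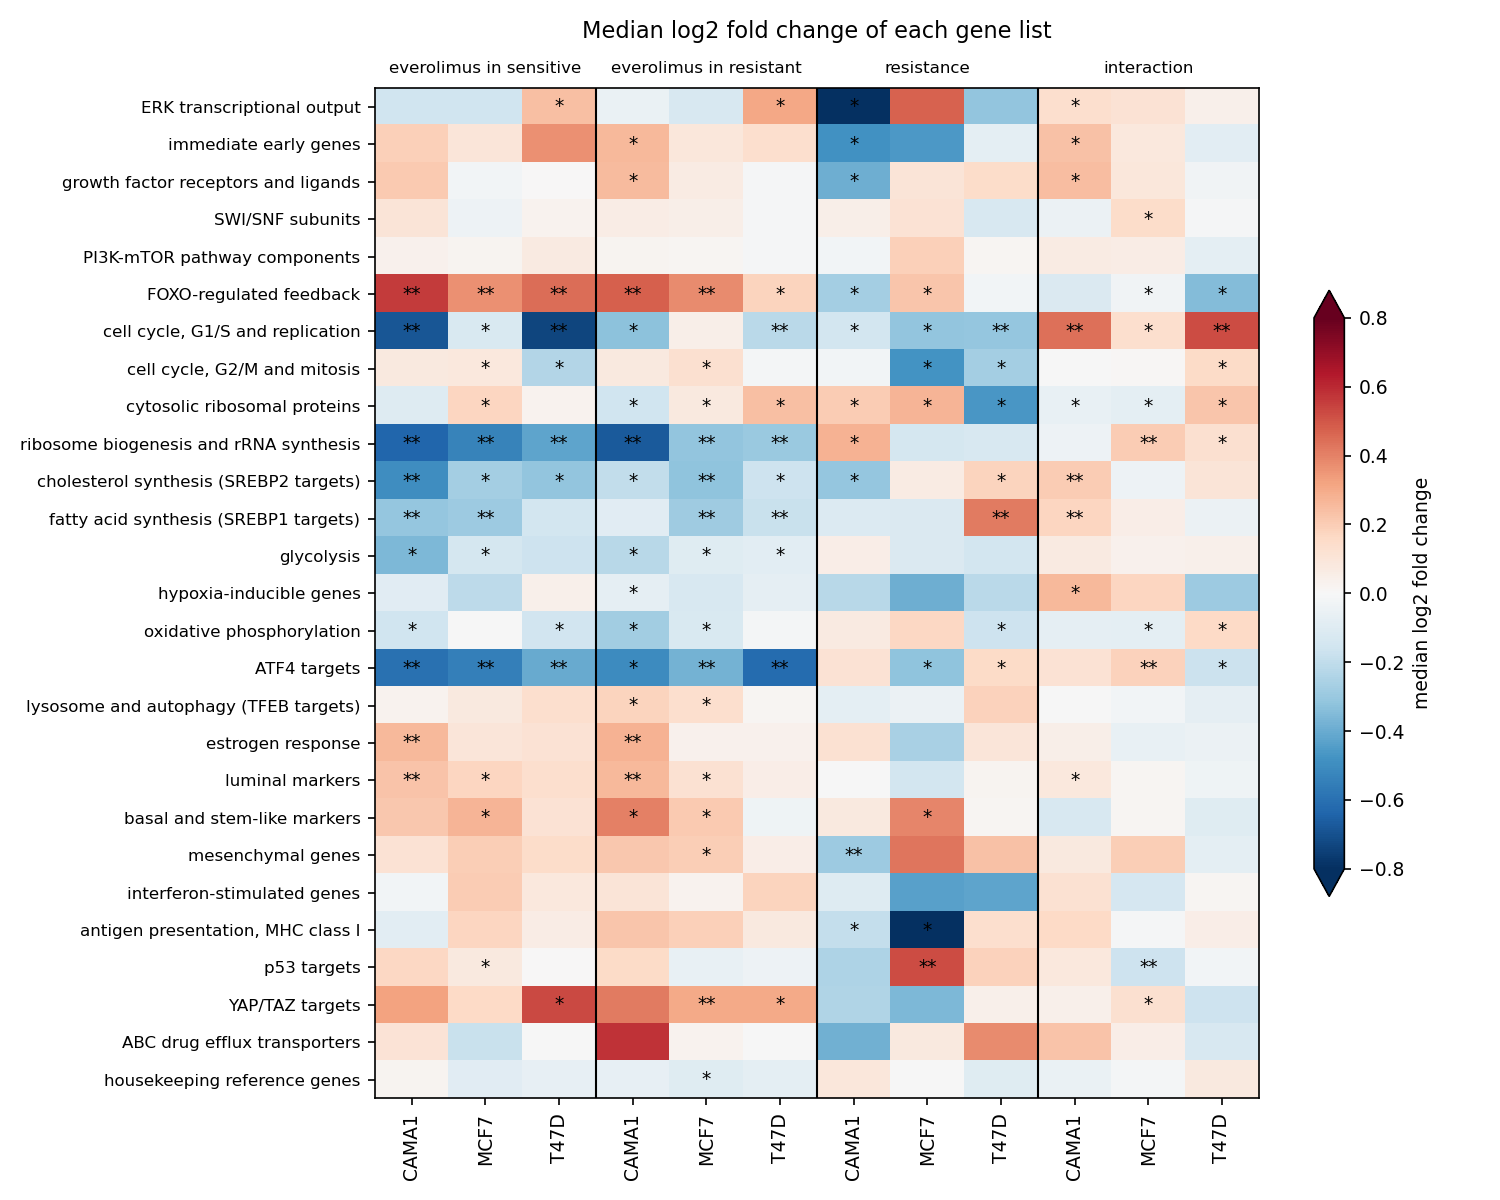
Median log2 fold change of each gene list in each comparison and line, as a heat map with blue for lower and red for higher, where one asterisk marks a camera call at a Benjamini-Hochberg threshold of 0.05 and a pair of asterisks a call that also held with an estimated correlation. The ribosome biogenesis medians lay between -0.67 and -0.30 in the 6 everolimus comparisons.

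The last comparison, the interaction, asked which genes responded to everolimus differently in resistant and sensitive cells. A positive value means a stronger rise or a weaker fall in resistant cells. The clearest group was G1/S and replication, whose fall under everolimus was weaker in resistant CAMA1 and T47D. In CAMA1 25 of 39 genes had a positive interaction (32 adjusted over the list alone), with a median of 0.44, and in T47D 31 of 39 (35 adjusted over the list alone), with a median of 0.52 (camera, Benjamini-Hochberg adjusted p = 1.52e-27 and 9.35e-37). Both calls held with an estimated correlation. In CAMA1 and T47D MCM10 had interactions of 0.77 ± 0.09 and 0.70 ± 0.10, FEN1, the flap endonuclease, of 0.76 ± 0.11 and 0.67 ± 0.09, CHAF1A, a histone chaperone, of 0.67 ± 0.11 and 0.99 ± 0.13, and CDC45 of 0.64 ± 0.10 and 0.88 ± 0.15. In MCF7 the list had 1 call (10 adjusted over the list alone) and a median of 0.13 (camera, Benjamini-Hochberg adjusted p = 2.21e-04 and adjusted p = 0.0619 with an estimated correlation).

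In MCF7 the falls of ribosome biogenesis genes (6 of 36 with a positive interaction, 15 adjusted over the list alone, median 0.20) and of ATF4 targets (6 of 28, 8 adjusted over the list alone, median 0.19) were weaker in resistant cells as lists, with few single genes called (camera, Benjamini-Hochberg adjusted p = 4.97e-11 and 1.29e-06, and 0.00442 and 0.00442 with an estimated correlation). SLC7A5 had an interaction of 0.43 ± 0.09 there, a call lost without resistant everolimus replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0551) and with limma on log2(TPM + 1) (Benjamini-Hochberg adjusted p = 0.0690). In T47D the interaction of SLC7A11 was -1.18 ± 0.21, a stronger fall in resistant cells, and that of DDIT4 was -0.76 ± 0.18. In CAMA1 cholesterol synthesis genes had a positive interaction for 6 of 23 (10 adjusted over the list alone), a call that held with an estimated correlation, with INSIG1, a sterol sensor, at 0.79 ± 0.12 and LDLR, the LDL receptor, at 0.51 ± 0.09. TXNIP rose less in resistant cells of each line, with interactions of -0.79 ± 0.08, -0.48 ± 0.08 and -0.63 ± 0.10. In T47D KLHL24 and PGR also rose less in resistant cells, with interactions of -0.78 ± 0.10 and -0.92 ± 0.11. Line differences in the interaction were not tested.

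An interaction in the same direction in all 3 lines was called for 23 positive and 7 negative genes, against 0.942 shared by independent lists. The positive ones included MCM10, ATAD3A, a mitochondrial membrane ATPase (0.63 ± 0.10, 0.59 ± 0.11 and 0.59 ± 0.14), and SRRT, an RNA processing factor (0.68 ± 0.14, 0.56 ± 0.10 and 0.45 ± 0.11), whose T47D call was lost with limma on log2(TPM + 1) at a Benjamini-Hochberg adjusted p of 0.169. The negative ones included TXNIP.

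The interaction was called for 1014, 360 and 1435 genes, 39, 11 and 41 of them at least 2-fold, with splits of 540 and 474, 240 and 120, and 681 and 754. With limma on log2(TPM + 1) the splits became 372 and 511 in CAMA1 and 304 and 1237 in T47D, and DESeq2 gave 212 and 166 in MCF7. These counts moved by more than 1.5 times without single libraries: in CAMA1 without sensitive DMSO replicate 2 (584) or 3 (591), sensitive everolimus replicate 1 (554) or 3 (618) or resistant DMSO replicate 1 (477), in T47D without sensitive DMSO replicate 2 (737), sensitive everolimus replicate 3 (723), resistant DMSO replicate 1 (927) or resistant everolimus replicate 3 (918). In MCF7 they did so without sensitive DMSO replicate 2 (220) or 3 (213), sensitive everolimus replicate 1 (164) or 2 (632), resistant DMSO replicate 1 (189) or 3 (197) or resistant everolimus replicate 2 (180), and the count shared by all lines did without MCF7 sensitive DMSO replicate 3 (19), sensitive everolimus replicate 1 (19), resistant DMSO replicate 1 (18) or 3 (18) or resistant everolimus replicate 2 (16).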

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

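Tests of residuals, of thinned counts, of TPM per count, of the G1/S genes under everolimus and of response ratios were chosen only after the results were seen. The differences between lines and between sensitive and resistant cells given here were found by a test of the difference itself, and other counts are given only beside their splits.

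The response to everolimus differed between resistant and sensitive cells for 1014 genes in CAMA1, 360 in MCF7 and 1435 in T47D. Regrouping the libraries of a line left the everolimus effect of one state inside the interaction, so that 2 of 33 splits gave as many genes in CAMA1 (highest other 1070), 2 of 33 in MCF7 (2212) and 4 of 33 in T47D (3233), and these splits do not exclude chance. When residuals of a fit without the interaction were reassigned among libraries, with limma on log2 CPM, the real counts of 983, 296 and 1407 were reached in 1, 2 and 1 of 100 assignments, the real one included (highest other 8, 662 and 2), which excludes spread between libraries alone in CAMA1 and T47D. In MCF7 the share is also small, but 1 other assignment gave over 2 times the real count, so the evidence there is weak. For the 30 interaction genes shared by all lines, 2 of 100 split draws gave as many (highest other 140), but these draws move the everolimus effect too. Residuals reassigned in each line gave the 27 genes that limma shared in 1 of 100 assignments, the real one (highest other 0). Other assignments gave at most 8 genes in CAMA1 and 2 in T47D, which left almost nothing to share. This test therefore speaks only against no interaction in any line, and does not show that the MCF7 part of the shared genes is real. The 1845, 823 and 566 genes shared under everolimus in sensitive cells, in resistant cells and with resistance were reached by 1 of 100 split draws, the real one (highest other 0 each). Any other split of a line gave 0 genes, so every other draw shared 0. These draws speak only against no effect in any line, and cannot show that the lines share genes beyond chance. Independent lists, with every gene equally likely to be called, would share 230, 80.2 and 367 genes. For resistance, 32% of the 1771 genes called in all 3 lines went in the same direction.

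For the 9 comparisons of 3 against 3 libraries within a line only 10 splits exist, too few to give a share under 0.05. The real split was the 1 of 10 with as many genes each time. Real counts were 6297, 5001 and 4396 for everolimus in sensitive cells, 6795, 3660 and 1950 in resistant cells, and 5283, 8286 and 5714 for resistance, and the highest other split gave 0 genes past Benjamini-Hochberg adjustment in edgeR in each, with at most 206 to 1418 genes at an unadjusted p under 0.05. The 121 list calls of camera were reached by 1 of 100 split draws, the real one (highest other 111). Regrouping leaves part of the effects in the comparison and moves part into the spread between libraries. These draws are therefore not draws without an effect, and cannot exclude chance for the total. Other splits, which carry part of the effects, gave 3 to 14 list calls against 7 to 15 real ones and reached the real number in 5 of these 9 comparisons, and for the interaction 13, 10 and 19 of 32 other splits did in CAMA1, MCF7 and T47D, so chance is not excluded for single list calls.

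The resistance effect differed between lines for 9205 genes, reached by 1 of 25 splits (highest other 4538) and by 1 of 100 residual assignments (real 9684, highest other 2094). The everolimus effect in sensitive cells differed between lines for 3415 genes, reached by 3 of 25 splits (highest other 6223), which mix the treatment of one line into the difference, and by 1 of 100 residual assignments (real 3420, highest other 1). A total of 1205 genes were called for resistance in all 3 lines with directions that differed. Lists with opposite calls between lines had 20 of 22 FOXO-regulated genes, 76 of 77 ribosomal protein genes, 20 of 23 cholesterol synthesis genes and 22 of 29 ATF4 targets that differed by line in resistance, and 25 of 33 G2/M genes in the everolimus effect. None of these opposite list calls held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0615 to 0.674), and 20 of 20 housekeeping genes also differed by line in resistance, so such shares are not particular to these lists. The log2 fold changes with resistance of fixed genes spanned 0.85 for ESR1, 2.12 for PGR, 2.36 for EGFR, 1.72 for ERBB2, 0.52 for ERBB3, 3.59 for ERBB4, 1.81 for FGFR1, 0.47 for FKBP1A, 0.78 for CCND1, 0.72 for MYC and 2.34 for DUSP6 between lines.

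Ribosomal protein genes were higher in resistant CAMA1 and MCF7 and lower in resistant T47D, with medians of 0.205, 0.270 and -0.467 in counts and the same signs in TPM (0.156, 0.188 and -0.238, or 0.183, 0.278 and -0.400 less the median of all genes). Genes matched on transcript length, GC content and expression had medians of 0.020, 0.039 and -0.120, and in T47D the matched genes also fell (95% interval -0.190 to -0.076) by part of the change. This interval came from resampling the matched genes and does not cover the spread between libraries. Length and GC content were those of the longest annotated transcript of a gene, with a median length of 1857 for ribosomal protein genes. That transcript need not be the one expressed, so the match cannot decide on a length or GC bias. Reads shared with pseudogenes stay open, because TPM per count of these genes hardly varied between libraries (median SD 0.040 on log2, 0.059 for other genes), so the TPM table was not the separate assignment of reads that its test assumed. A difference between resistant cells of the lines in ribosomal protein transcripts stays a candidate explanation, with the caveat that no list call held with an estimated correlation and that culture differences between resistant and sensitive cells were not tested.

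G1/S and replication genes fell less under everolimus in resistant CAMA1 and T47D, with median interactions of 0.438 and 0.513 on log2 CPM that 1 of 100 residual assignments reached in each line (highest other 0.347 and 0.393), and thinned counts argue against depth, with medians of 0.424 and 0.528. A weaker response as a whole is argued against as the only cause by ribosome biogenesis genes in CAMA1, which kept 1.05 of their response in resistant cells against 0.48 for the G1/S genes, although cholesterol synthesis genes there (0.39) also weakened. In T47D the median absolute log2 fold change of all genes was 0.21 in sensitive and 0.15 in resistant cells. Of 1172 interaction genes also called in sensitive cells, 1121 were weaker in resistant cells. Choosing genes by their call in sensitive cells favors that direction, so this count decides nothing. In CAMA1 it was 456 of 655, with medians of 0.27 and 0.29. Ribosome biogenesis genes in T47D kept 0.70 (95% interval 0.59 to 0.90) and ATF4 targets 1.52, against 0.30 (0.22 to 0.38) for the G1/S genes. FOXO-regulated genes kept 0.39 (-0.01 to 0.67) and cholesterol synthesis genes 0.53 (0.36 to 1.03), so a weaker response as a whole may be part of the cause. A lower starting level in resistant cells, with the same level under everolimus, is argued against as the only cause in CAMA1, where resistant cells lay higher under everolimus by each of 3 summaries of the list per library (smallest 0.177, 95% interval 0.118 to 0.235). In T47D it cannot be told apart from a weaker response of these genes, since the summaries gave 0.210 (0.175 to 0.245), 0.188 (0.135 to 0.240) and 0.016 (-0.077 to 0.109), of which the last includes 0, and camera called the list under everolimus in CAMA1 (21 genes higher, 1 lower) and T47D (17 and 3) with the preset correlation (Benjamini-Hochberg adjusted p = 2.84e-04 and 0.0102) but not with an estimated one (0.225 and 0.342). Whether resistant cells were kept in everolimus before is not stated, and an effect of earlier drug on their DMSO level was not tested.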

How the results depend on the processing

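Thinning of counts and list tests under everolimus were chosen after the data were seen, and the other alternatives were planned. Counts of genes stayed within 1.5 times of the main count under RLE size factors, DESeq2, both filters, only the 6 libraries compared and resistance measured under everolimus, for every result these were run on. Against a fold change of 1.5, glmTreat called 588, 113 and 76 genes for everolimus in sensitive CAMA1, MCF7 and T47D and 19 shared, 744, 36 and 5 in resistant cells and 1 shared, and 762, 2106 and 649 for resistance and 17 shared, since it asks for a larger change. For the interaction it called 2, 0 and 0 and shared 0 (edgeR, where an unadjusted p under 0.05 gave 89 genes in MCF7 and 169 in T47D, against 360 and 1435 by the main edgeR test and 378 and 1601 by DESeq2). The MCF7 interaction gave 142 genes after thinning, which removes counts, 76 and 83 on log2(TPM + 1) and log2(TPM + 0.1), and 133 in a fit of all 36 libraries, which gave 2161 in T47D. The shared interaction count was 11 after thinning, 15 and 15 with TPM and 12 with all 36 libraries, and the cause was not tested. List calls fell from 121 to 41, with 80 lost, when camera estimated the correlation between list genes instead of taking the preset one. Those 80 calls therefore depended on the preset correlation. For resistance in CAMA1 the estimate was 0.724 for ribosomal protein genes, but 0.000 for MAPK output genes, and both calls were lost. A high correlation between list genes therefore does not account for every loss. Of the list calls, 9 were lost and 6 gained after thinning, 1 lost and 2 gained with RLE factors, 5 lost and 3 gained with the stricter filter, and 9 lost and 17 gained without a filter. Resistance measured under everolimus turned the direction of EGFR in T47D (-0.559), MCM5 in CAMA1 (0.142, not called, edgeR, Benjamini-Hochberg adjusted p = 0.102) and T47D (0.338) and PGR in T47D (-0.653). It ended the calls of B2M and CCND1 in CAMA1, PHF10 in MCF7 and IGF1R in T47D (edgeR, Benjamini-Hochberg adjusted p = 0.105, 0.725, 0.794 and 0.614). Everolimus acting differently in both states is part of that setting. With TPM the median log2 fold change of all genes, at most 0.025 from 0 in counts, lay over 0.1 from 0 in CAMA1 for everolimus (0.134 in sensitive and 0.111 in resistant cells) and in T47D for everolimus in sensitive cells (0.106), resistance (0.162) and the interaction (-0.131).

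The replicate numbers did not pair the libraries: of 54 same-numbered pairs 3 had a correlation of deviations over 0.1 (median 0.015, range -0.19 to 0.18). With the number as a block, everolimus in resistant T47D gave 1588 genes and the T47D interaction 1133, and all other counts also stayed within 1.5 times, with 3 list calls gained and 1 lost.

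Leaving out 1 library gave ranges of 5476 to 5802, 4121 to 4763 and 3210 to 4069 for everolimus in sensitive cells and 1519 to 1808 shared, of 5889 to 6768, 2837 to 3261 and 994 to 1813 in resistant cells and 464 to 811 shared, of 4370 to 4603, 7672 to 7867 and 4788 to 5673 for resistance and 470 to 542 shared, and of 477 to 1245, 164 to 632 and 723 to 1798 for the interaction and 16 to 44 shared. Such a fit leaves 2 libraries in a group. The list calls numbered 116 to 125. With 3 libraries per group, the simulated 1.5-fold changes of the resistance comparison were recovered for 65.7% of genes in CAMA1. The simulation changed only 67, 67 and 66 genes there at 1.5-, 2- and 4-fold, against 5283 called in the data. The called genes had a median absolute log2 fold change of 0.40, so the simulation cannot tell how small a change was detectable in the data.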

Other observations

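Tests of thinned counts and of MTRNR2L reads were chosen only after the results were seen.

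Single genes of further groups changed in resistant cells. Interferon-stimulated genes were lower in resistant MCF7 for 12 of 21 genes and higher for 6, and in T47D lower for 11 of 24 and higher for 1 (12 and 11 lower adjusted over the list alone), without a camera call (Benjamini-Hochberg adjusted p = 0.396 and 0.0569). Among the higher genes, SAMD9 rose by 4.36 ± 0.18 in MCF7. Antigen presentation genes were lower in resistant MCF7 for 8 of 11 (8 adjusted over the list alone, camera Benjamini-Hochberg adjusted p = 0.00709, adjusted p = 0.121 with an estimated correlation). There the peptide transporter genes TAP1 and TAP2 fell by -1.35 ± 0.09 and -1.86 ± 0.13. B2M, the shared light chain, fell by -1.08 ± 0.06 in MCF7 and rose by 0.23 ± 0.06 in CAMA1 (0.124 and no call with both states under everolimus) and 0.46 ± 0.06 in T47D (line difference by edgeR, Benjamini-Hochberg adjusted p = 4.99e-20).

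Drug transporter genes also differed by line. ABCC3 fell by -3.05 ± 0.61 in resistant CAMA1 and rose by 0.66 ± 0.15 in T47D (line difference by edgeR, Benjamini-Hochberg adjusted p = 4.37e-06), and ABCG2 fell by -1.42 ± 0.12 in MCF7. The lactate dehydrogenase gene LDHB fell by -3.98 ± 0.38 in resistant T47D and the glucose transporter SLC2A1 rose by 0.96 ± 0.09 there. Under everolimus the adhesion receptor CD44 rose by 1.73 ± 0.37 and 0.38 ± 0.07 in sensitive CAMA1 and MCF7, and CTSF, the lysosomal protease cathepsin F, by 0.80 ± 0.06 and 0.31 ± 0.07 in CAMA1 and T47D.

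Everolimus called more genes in sensitive CAMA1 (6297) than in the other lines, and the everolimus libraries of that group were shallower than its DMSO libraries. After thinning all 12 CAMA1 libraries to 1 total, 5736 genes were called, 5579 of them called in the same direction before, which argues against depth as the source of the higher count. MTRNR2L genes, copies of a mitochondrial rRNA segment whose reads cannot be assigned with certainty, rose in the same group from a sum of 3.4 to 41.9 CPM (14 to 27 CPM in resistant CAMA1). Over 36 libraries and 10 genes the deviations of MTRNR2L CPM and library total from their group means correlated with r = -0.86 (permutation p = 0.00032) and rho = -0.72 (permutation p = 5e-04), and r was -0.73 without the 2 libraries farthest in depth, so shallow libraries carrying more of these reads may explain part of the rise in CAMA1. Under everolimus the sum rose in resistant MCF7 in the shallowest library alone (32.61 CPM, against 1.364 and 2.958 in the others) and not in sensitive MCF7 (1.7 to 1.5), but it rose in resistant T47D (8.07 to 19.8 CPM) and in sensitive T47D (7.92 to 15.6), where the everolimus libraries were deeper on average, so depth does not account for every rise, and an effect of everolimus and RNA quality, which the labels do not give, stay open.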
